A study of Homo sapiens with 4 samples.

How the data were processed

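The 4 libraries are bulk polyA RNA sequencing (paired-end, 75 bp) of neurons transduced at 2 weeks with lentivirus at a multiplicity of infection of about 3, kept in puromycin at 0.5 μg/mL for 4 days and collected 7 days after the virus, per the labels' protocols. The labels state that replicates were biologically independent and that 2 guide RNAs were used per element; which guide went into which library was not given in the sources used here. The deposited files hold, for each gene, a whole-number read count and an FPKM-like value, both computed by the authors before deposit. Per the submitters' processing notes the genome build is hg38 and the tools include edgeR and limma, without versions; the aligner, the counting tool and the strand setting were not given in the sources used here. Counts of overlapping or antisense genes and of near-identical copies are therefore uncertain. Of the deposited values only the counts were tested. The FPKM values were not used in tests, because between 602 and 954 rows per library held a count but an FPKM of 0.

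Counts were summed per gene symbol over all rows, which include alternate and fix contigs (5.08% to 5.15% of counts). Of 28307 symbols, 27202 matched RefSeq by symbol and 544 by synonym, and 561 did not match. Positions come from RefSeq on GRCh38 and, for the targeted intervals and the pair of genes beside them, from GENCODE release 29. The build of the 2 stated intervals was not given beside them and was taken to be that of the processing notes.

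CRISPRi was compared with control by edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, robust quasi-likelihood F test, Benjamini-Hochberg threshold 0.05), with the group as the only term. Confidence intervals of 95% and standard errors derive from the F statistic. edgeR raises p to a Poisson bound for genes with less than Poisson spread, which applied to 1704 genes, PTPMT1 among the named ones; without the bound the calls were 0 higher and 4 lower. Fold changes weight libraries by depth, whereas mean ± SD values weight them equally. With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.333, so none is given. No pair of libraries was treated as a duplicate. Intervals on counts cover counting error only.

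Gene lists (32, fixed before the data were examined, 30 with at least 3 tested members) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, and again with an estimated correlation and with fry. Lists of mitochondrially encoded and microglial genes had 0 and 1 tested members. The 12 lists described are the 6 that passed and 6 chosen after their values were seen. Named genes followed a rule fixed before the data were examined: C1QTNF4, MTCH2 and tested genes within 100 kb; up to 12 genes per direction past the threshold, or the 5 with the smallest p where fewer than 5 passed; and the members with the smallest p in each described list, of which 3 were computed. Not every gene taken by this rule is reported here. SLC39A13, PACSIN3, AGBL2, FAM180B, PAK6, MKI67, TOP2A and the other 18S copies were named after their values were seen.

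Alternatives fixed before the data were examined were median-of-ratios and total-count scaling, no filter and a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, an adjusted p under 0.01, a test against a fold of 1.5, protein-coding genes only, and windows of 100 kb and 1 Mb. Thinning of the deep libraries to the depth of control replicate 1, and camera on negative-binomial scores, were added after the data were seen. The test was tried on simulated counts of 15517 genes with 200 changed genes, where it made 5 false calls.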

Results

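Gene expression was measured by polyA RNA sequencing in excitatory neurons derived from WTC11, a human induced pluripotent stem cell line, in which a catalytically dead Cas9 fused to the KRAB repressor domain had been knocked into an intron of CLYBL. This arrangement, CRISPR interference (CRISPRi), is used to silence the stretch of DNA that a guide RNA matches. Groups of 2 libraries were compared, 2 libraries from neurons given guides against 1 element of the MIR family of transposable elements on chromosome 11, and 2 libraries from neurons given the empty guide vector. Total gene counts were 44839748 and 41560282 in CRISPRi replicates 1 and 2 and 39325038 in control replicate 2. Control replicate 1 held 944993 counts, 41.6 times fewer than the shallowest of the other 3 libraries. In that library 1 count equals 1.06 CPM (counts scaled to a common library total), and 13503 genes had a count, against 18702 to 18865 in the others.

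The first question was whether genes near the targeted element changed. The element's position is given in 2 ways, as chromosome 11 from 47605296 to 47605575 and as chromosome 11 from 47608036 to 47608220, intervals of 280 bp and 185 bp that lie 2460 bp apart. No feature of GENCODE release 29 overlaps either interval on GRCh38. Both lie between C1QTNF4, a secreted protein of the C1q and TNF related family (47589664 to 47594659, minus strand), and MTCH2, a protein of the outer mitochondrial membrane (47617315 to 47642623, minus strand). RefSeq gives MTCH2 a longer extent, from 47604317 to 47642559, which contains both intervals.

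No gene near the element passed the test. C1QTNF4 was at 16.2 ± 2.09 CPM in CRISPRi neurons and 15.6 ± 0.0771 CPM in controls (mean ± SD, n = 2 each), a log2 fold change of 0.06 with a 95% confidence interval of -0.35 to 0.46. MTCH2 was at 179 ± 0.00932 CPM and 166 ± 21.2 CPM (mean ± SD, n = 2 each), a log2 fold change of 0.08 with an interval of -0.17 to 0.32. Both intervals exclude a halving. The sign of C1QTNF4 turned without CRISPRi replicate 1 (-0.08), and that of MTCH2 turned without control replicate 1 (-0.02). The counts behind the C1QTNF4 values were 789, 606, 15 and 610 in CRISPRi replicates 1 and 2 and control replicates 1 and 2.

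**Figure D1:**
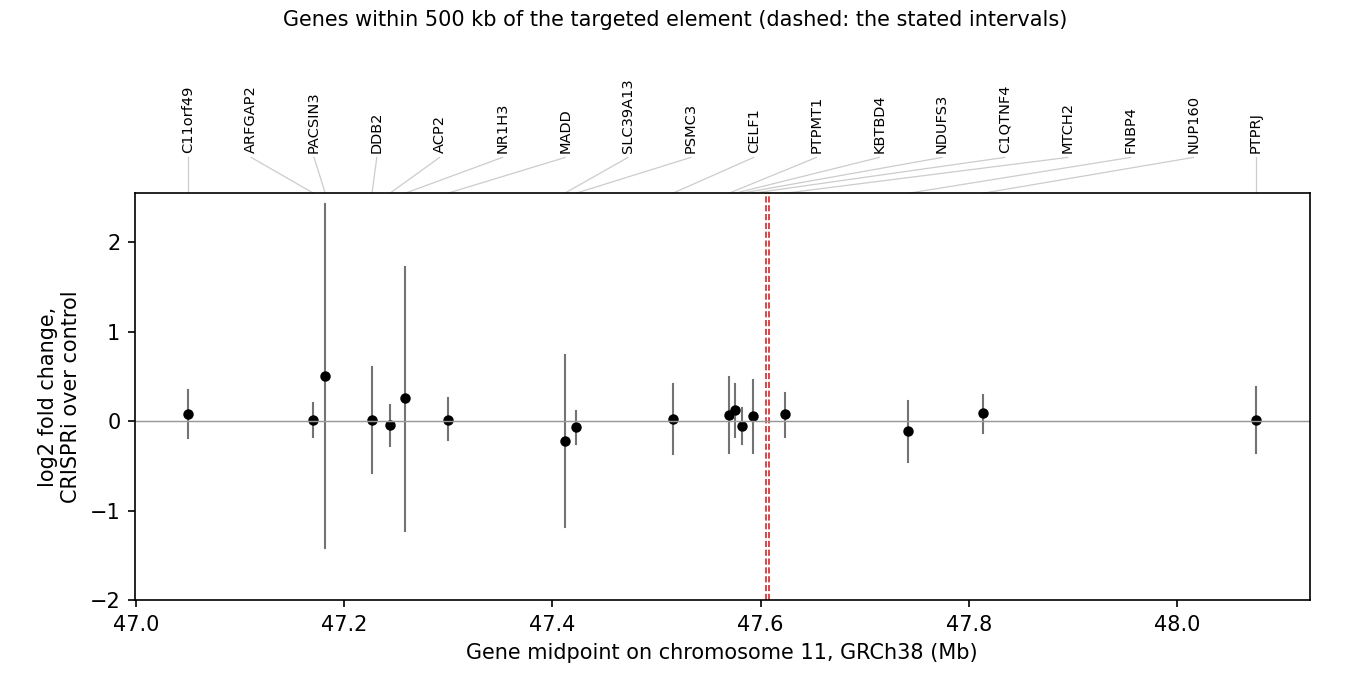
Log2 fold change of CRISPRi over control (points) with 95% confidence intervals (lines) for the 18 tested genes within 500 kb of the element, by gene midpoint on chromosome 11 (GRCh38, Mb); dashed lines mark the 2 stated intervals. Every interval includes 0.

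The other genes tested within 100 kb were CELF1, an RNA-binding protein (log2 fold change 0.03), the mitochondrial phosphatase PTPMT1 (0.07), KBTBD4 (0.13) and the complex I subunit NDUFS3 (-0.05). Over all 18 tested genes within 500 kb, fold changes ran from -0.22 for SLC39A13 to 0.51 for PACSIN3, which had 1 to 16 counts per library and whose equally weighted means go the other way (0.313 CPM in CRISPRi, 0.611 CPM in controls). By edgeR's quasi-likelihood test 0 of the 18 passed, 0 passed when adjusted over the list alone, and 0 had an unadjusted p under 0.05. DESeq2 and limma-voom also called 0. For 15 of the 18 the interval excluded a halving. The median log2 fold change was 0.03, at percentile 63.9 of 10000 random runs of as many neighbouring tested genes. AGBL2 had 0 counts in every library, and FAM180B had 3 to 8 counts in the deep libraries and 0 in control replicate 1 and was not tested.

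Across the transcriptome 4 of 15708 tested genes were called lower in CRISPRi neurons and 0 higher. MMGT1, a membrane magnesium transporter that is also a subunit of the endoplasmic reticulum membrane complex, fell from 76.7 ± 5.16 CPM in controls to 13.6 ± 0.525 CPM (mean ± SD, n = 2 each). UBE2G2, a ubiquitin-conjugating enzyme of endoplasmic reticulum-associated degradation, fell from 77.7 ± 2.37 to 20.5 ± 0.229 CPM (mean ± SD, n = 2 each). C4orf3, a small membrane protein, fell from 96.3 ± 3.34 to 30.1 ± 3.33 CPM (mean ± SD, n = 2 each). The fourth was RNA18SN5, 1 of several near-identical copies of the 18S ribosomal RNA gene.

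The log2 fold changes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were -2.47 for MMGT1 (SE 0.10, adjusted p = 0.00666), -1.91 for UBE2G2 (SE 0.09, adjusted p = 0.00666) and -1.69 for C4orf3 (SE 0.11, adjusted p = 0.0292). MMGT1 lies on chromosome X (135960588 to 135973988), UBE2G2 on chromosome 21 (44768580 to 44801820) and C4orf3 on chromosome 4 (119296419 to 119304445). C4orf3 did not pass with limma-voom (log2 fold change -1.71), nor with a filter of 1 CPM in 2 libraries (-1.69). MRPS27, a mitochondrial ribosomal protein, came next (log2 fold change -1.34, edgeR adjusted p = 0.0598) and did not pass, although it passed with no filter on low counts, with DESeq2, with the replicate block and with each library left out in turn (-1.29 to -1.45). Its level was 24.4 ± 0.693 CPM in CRISPRi neurons and 63.2 ± 5.15 CPM in controls (mean ± SD, n = 2 each).

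RNA18SN5 had 1 and 1 counts in the CRISPRi libraries and 508 and 12755 in the controls, a control over CRISPRi ratio of 14200 with a counting interval of 3940 to 117000. Counts of its copies were placed alike in the CRISPRi libraries and differently in each control: RNA18SN4 had 15820 and 14285 counts in CRISPRi and 1414 and 1 in control replicates 1 and 2. RNA18SN2 had 43880, 39627 and 35456 counts in the deep libraries and 0 in control replicate 1. Summed over the copies, 18S counts were at 2350 and 2290 CPM in CRISPRi and 3590 and 2160 CPM in control replicates 1 and 2, so the value of a single copy is uncertain. RNA18SN5 did not pass with limma-voom or after the deep libraries were thinned to the depth of control replicate 1, with fitted log2 fold changes of -13.31 and -11.7 against -13.9.

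**Figure D2:**
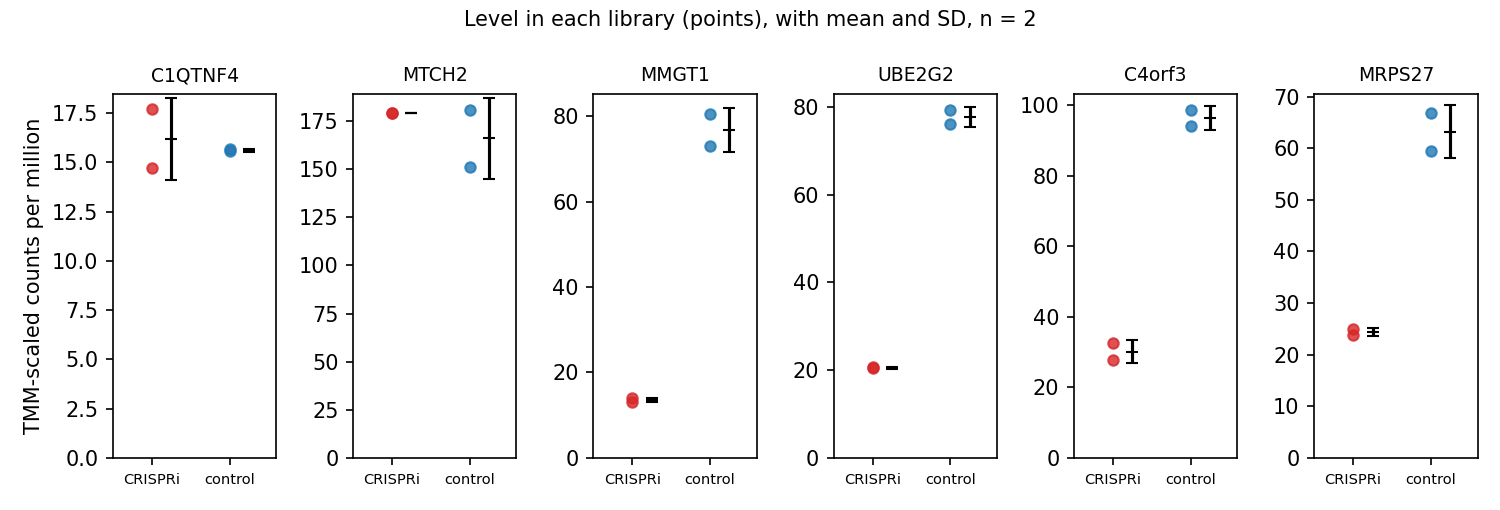
TMM-scaled CPM (axes start at 0) of C1QTNF4, MTCH2, MMGT1, UBE2G2, C4orf3 and MRPS27 in each CRISPRi (red) and control (blue) library, with mean and SD (n = 2) in black. MMGT1 sits at 13.2 and 14 CPM in the CRISPRi libraries and at 80.4 and 73.1 CPM in the controls.

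No gene rose by edgeR, with 86 genes higher at an unadjusted p under 0.05; DESeq2 called 1 and limma-voom 0. The 5 genes with the smallest p in that direction did not pass by edgeR on all 4 libraries, although each passed without control replicate 1. BUB1B-PAK6, a read-through transcript, had 213 and 173 counts in CRISPRi and 0 in both controls, at least 60-fold higher against a floor of 3 counts over the control group; the lower limit of the counting interval of the ratio was 48.5. It overlaps PAK6, a kinase gene that had 64 and 40 counts in CRISPRi and 4 and 196 in control replicates 1 and 2, so that the division of reads between the pair is uncertain; their sum was at 6.18 and 5.13 CPM in CRISPRi and 4.23 and 4.98 CPM in controls. BUB1B-PAK6 also passed with DESeq2 and with the replicate block. PRKG2, a cGMP-dependent protein kinase, was at 55.2 ± 1.42 CPM against 33.2 ± 2.62 CPM, and ANKRD44 at 20.9 ± 0.674 CPM against 10.6 ± 0.225 CPM (mean ± SD, n = 2 each). AGFG1 was at 97.3 ± 2.22 CPM against 69.1 ± 3.3 CPM and LOC107985115 at 34 ± 2.08 CPM against 14.9 ± 4.77 CPM (mean ± SD, n = 2 each). PRKG2 and LOC107985115 passed with the replicate block too (log2 fold changes 0.7 and 1.07), whereas ANKRD44 and AGFG1 did not. Without control replicate 2 the log2 fold changes were 10.02 for BUB1B-PAK6, 0.82 for PRKG2, 1 for ANKRD44, 0.54 for AGFG1 and 1.57 for LOC107985115.

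The counts of called genes moved with the libraries used. Without control replicate 1 there were 71 higher and 36 lower genes, and without control replicate 2, 580 higher and 798 lower; without CRISPRi replicate 1 there were 2 and 15, and without CRISPRi replicate 2, 4 and 29. Each of these included the 4 genes above. Of the 71 genes higher without control replicate 1, that library lay nearer to CRISPRi than to control replicate 2 for 59, and of the 34 lower genes that were also tested with all 4 libraries, for 9. In data simulated at these depths the test recovered 15 of 50 genes changed 1.5-fold and 32 of 50 changed 2-fold. It recovered 39 of 50 changed 3-fold and 35 of 50 changed 4-fold. Whether these shares hold for the real counts was not tested, so they do not give the power of the comparison. With all 4 libraries the smallest called change was that of C4orf3 (log2 fold change -1.69). ANKRD44, with a log2 fold change of 0.96 (SE 0.14), had an edgeR adjusted p of 0.617.

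Of 30 gene lists tested, 6 passed with camera at a preset correlation of 0.01, and 0 passed with an estimated correlation or with fry. No member of any of these lists was called over all genes, and 0 were called when adjusted over the list alone. The list of cell cycle genes was lower in CRISPRi (20 of 20 members with a negative fold change, median -1.25, camera adjusted p = 2.24e-06; adjusted p = 0.863 with an estimated correlation). The high values lay in control replicate 1, where the mitotic genes MKI67 and TOP2A were at 75.2 and 79.3 CPM, and between 11.1 and 14.3 CPM in the other 3 libraries. AURKB, a mitotic kinase, was at 25.1 CPM in control replicate 1 and 1.35 CPM in control replicate 2.

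Cytoplasmic ribosomal proteins were lower as a list (29 of 30 members negative, median -0.13, camera adjusted p = 2.43e-05; adjusted p = 0.863 with an estimated correlation), and RPS2 was at 1010 CPM in CRISPRi against 1560 and 1030 CPM in control replicates 1 and 2. The list of stress and unfolded protein response genes was lower too (18 of 22 negative, median -0.12, camera adjusted p = 0.00296; adjusted p = 0.863 with an estimated correlation). Among these the stress-response transcription factor ATF4 had a log2 fold change of -0.23 and the serine synthesis enzyme PHGDH one of -0.35, and both were at -0.13 without control replicate 1. Cholesterol biosynthesis genes were lower as a list (17 of 23 negative, median -0.1, camera adjusted p = 0.00296; adjusted p = 0.863 with an estimated correlation), with LSS at -0.24 and DHCR7 at -0.19, and at -0.09 and -0.11 without control replicate 1.

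Pan-neuronal genes were higher as a list (19 of 20 members positive, median 0.13, camera adjusted p = 0.0153; adjusted p = 0.863 with an estimated correlation). The intermediate filament gene INA was at 2480 CPM in CRISPRi and 2190 ± 261 CPM in controls (mean ± SD, n = 2). Mesenchymal genes were higher as a list (19 of 20 positive, median 0.16, camera adjusted p = 0.00296; adjusted p = 0.863 with an estimated correlation), although TAGLN, an actin-binding protein, had a log2 fold change of -1.01 (edgeR adjusted p = 1). The shift of both lists lay in control replicate 1, at -0.23 for pan-neuronal genes against -0.02 to 0.01 in the other 3 libraries, and at -0.78 for mesenchymal genes against -0.07 to 0.13 (median log2 CPM relative to the 3 deep libraries). THY1, which stands in both lists, differed from this and was at 186 and 185 CPM in CRISPRi, 166 CPM in control replicate 1 and 66.7 CPM in control replicate 2. Its log2 fold change, 0.92 in the main comparison, was 1.48 without control replicate 1 and 0.16 without control replicate 2. The list levels in control replicate 1 are also limited by its depth. Members with 0 counts there, such as the mesenchymal gene DCN, take a very low log2 CPM. How much of the -0.78 comes from depth was not tested. After the deep libraries were thinned to the depth of control replicate 1, 2 of the 6 lists still passed with camera. Without control replicate 1, 0 of the 30 lists passed.

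**Figure D3:**
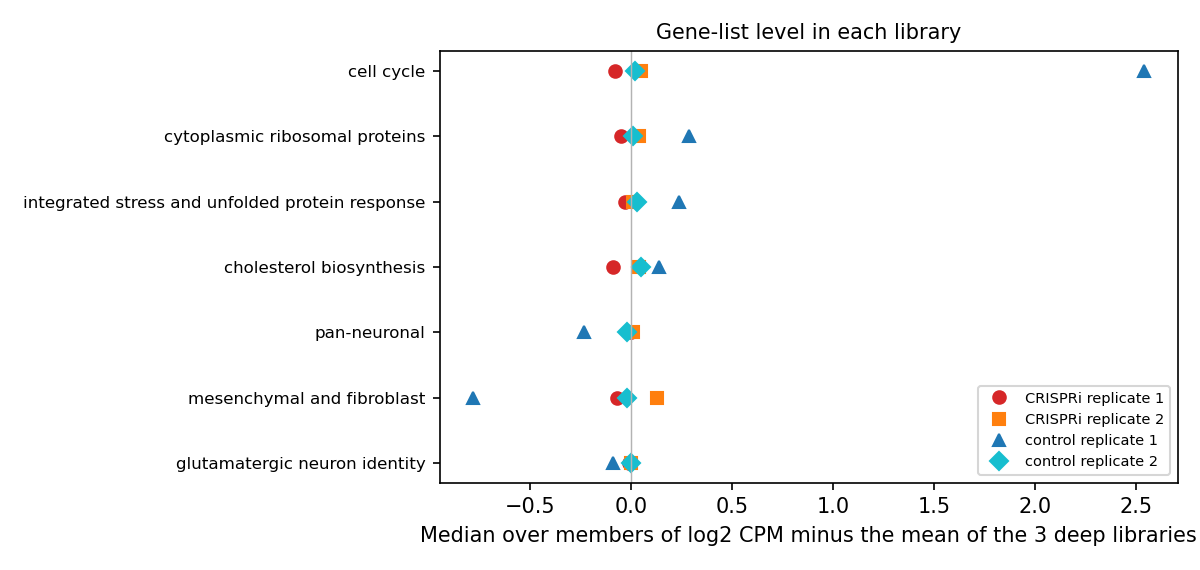
Median over each list's members of log2 CPM minus the mean of the 3 deep libraries, per library (symbols). Control replicate 1 lies at 2.54 for cell cycle genes and at 0.29 for ribosomal proteins, while the other 3 libraries lie between -0.08 and 0.05 for both.

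No list of neuronal identity genes other than the pan-neuronal one passed. Of 18 tested glutamatergic identity genes 0 passed, with a median log2 fold change of 0.04 (camera adjusted p = 0.74). The vesicular glutamate transporter SLC17A6 was at 160 CPM in CRISPRi and 146 ± 0.545 CPM in controls (mean ± SD, n = 2), and the receptor subunit GRIN2B had a log2 fold change of -0.27, or -0.06 without control replicate 2. Presynaptic genes had a median of 0.06 (camera adjusted p = 0.151), with the synaptotagmin SYT4 at 0.2, or 0.07 without control replicate 1. The presynaptic list did pass with camera on negative-binomial scores (adjusted p = 0.0372), a setting added after the data were seen. Markers of peripheral and autonomic neurons had a median of 0.02 (camera adjusted p = 0.621), and the intermediate filament PRPH was at 333 CPM against 283 ± 21.1 CPM (mean ± SD, n = 2). Genes of the C1q and TNF related family had a median of 0.08 (camera adjusted p = 0.74), with CBLN1 at 0.19, or -0.02 without control replicate 1. Genes of Alzheimer disease risk and pathways had a median of 0 (camera adjusted p = 0.717), and the protease ADAM10 had a log2 fold change of -0.34 (edgeR adjusted p = 1). The list of NF-kB and IL6-STAT3 response genes had a median of -0.24 (camera adjusted p = 0.621), with STAT3 at 0.51, or 0.19 without control replicate 2 and 0.66, past the threshold, without control replicate 1. ADAM10 (-0.38) also passed without control replicate 1. Leaving out control replicate 2 leaves control replicate 1 alone in its group. Log2 fold changes were then -0.34 for ATF4, -0.76 for PHGDH, -0.43 for LSS, 0.3 for INA and 0.31 for PRPH. They were 0.38 for SYT4, 0.55 for CBLN1, -0.63 for RPS2 and -4.02 for AURKB. The other 18 lists did not pass either.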

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

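Thinning to the depth of control replicate 1, camera on negative-binomial scores and, for the median near the element, all settings but the windows were chosen after the result was seen. The 0 calls near the element held under each setting run for them, which leaves out the adjusted p under 0.01, the test against a fold of 1.5 and protein-coding genes only. Genes higher in CRISPRi numbered 0 and became 1 with DESeq2, 17 with the replicate block, 1 after thinning, and 2 to 580 with a library left out. Genes lower numbered 4 and became 12 with DESeq2, 2 with limma-voom, 25 with the replicate block, and 15 to 798 with a library left out. With a library left out 1 group keeps a lone library, assumed to vary like the other group. The 6 lists called became 9 with DESeq2, 7 with camera on negative-binomial scores, 4 with limma-voom, 2 after thinning, 0 with an estimated correlation, 0 with fry, and 0 to 5 with a library left out. The median near the element, 0.03, became -0.04 after thinning and ran from -0.02 to 0.14 with a library left out. With a library left out C1QTNF4 ran from -0.08 to 0.18 and MTCH2 from -0.02 to 0.25. Signs turned, for genes that did not pass in the comparison of all 4 libraries, for CELF1 (-0.09 with limma-voom, -0.12 to 0.45 with a library left out), PTPMT1 (0 with limma-voom, rounded, -0.03 to 0.58 with a library left out, -0.19 after thinning), KBTBD4 (-0.1 after thinning), AURKB (-4.02 to 0.19 with a library left out), CAMK2B (0.39 after thinning), ISL1 (-0.06 after thinning), CBLN1 (-0.02 to 0.55 with a library left out) and PTK2B (0.15 after thinning). The cause was not tested. A value of 0.2 listed for AURKA after thinning was set aside, although it stands among the 12 sign turns counted below. Control replicate 1 lay above all 3 thinned libraries at 20 of 20 cell cycle genes, AURKA among them, which that sign contradicts. Of 580 values of the other 49 named genes under alternatives, 523 kept direction and side of the threshold, 4 lost a call, 41 gained one and 12 turned sign. Nothing in the labels says that replicate numbers pair the samples, and the correlation of deviations over genes, -0.03, decides little because it rests on control replicate 1. The depth of control replicate 1 limits low genes, since 3 counts there equal 3.18 CPM.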

Other observations

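The tests of control replicate 1, of neighbouring genes and of the splits were chosen only after the result was seen; the test of steps of matching size was set before its counts were computed, after weaker steps had been counted. Control replicate 1 differed from the other 3 libraries in more than depth, with 834 counts of cell cycle genes where the levels of the others predict 175. Low depth alone is argued against: after the others were thinned to its total, its cell cycle genes lay 2.26 higher on the log2(CPM + 1) scale (median, SD of the thinned libraries 0.24), 20 of 20 above all 3. RNA of another dividing cell type is a candidate source, and 293T cells, which packaged the virus before filtration and puromycin selection, are a hypothesis for it. Posterior HOX genes, listed by paralog group, summed to 140 counts (exact Poisson 95% interval 118 to 165) against 24.7 predicted. They were led by HOXB9 (58.2 CPM, against 17.1 CPM in the other 3 libraries) and HOXD13 (15.9 CPM, 0 counts in the other 3). Of the 16 listed genes, however, 9 also had counts in the others. Pluripotent cells stay open too: 10 fixed-list genes of low baseline summed to 25 counts (interval 16.2 to 36.9) against 14.1 predicted (the whole list of 15, with members of high baseline, showed no such excess, 229 with an interval of 200 to 261 against 213), from DNMT3B, USP44 and SOX2, while the other 7, L1TD1 and POU5F1 among them, had 0. A first version of that last test used 6 genes picked because they were at 0 and was replaced for that reason; cross-talk between libraries was not tested.

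MMGT1, UBE2G2 and C4orf3 were lower in both CRISPRi libraries, and none lies on chromosome 11. Reads counted to a neighbour instead are argued against, since neighbours within 5 kb changed by -2.91% of the 186 CPM lost (-5.42 CPM, SD 9.37). Steps between single libraries stay open. At a step of 2.83-fold, the smallest gap among the 3 genes, the CRISPRi pair was jointly lower at 2 to 4 genes. The highest other pair was so at 1 to 2, and in 0 of 6 combinations of level and averaging did another pair have as many. These counts are few, and the step was set from the CRISPRi pair's own genes. RNA18SN5, whose single-copy value is uncertain, also counts for the CRISPRi pair in each combination. Without RNA18SN5 the combination at 2 genes against 1 would no longer favour that pair. At weaker steps of 1.5-fold and 2-fold another pair had as many in 11 of 12 combinations. The 4 libraries allow 3 splits into pairs, too few for a share under 0.05; 1 split, the real one, called 4 genes and the highest other called 1. Silencing by the guides at other sites remains open, as untested, because guide sequences were not used here.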
